A study of Homo sapiens with 9 samples.

How the data were processed

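Gene expression was measured on 9 Clariom S arrays hybridized with RNA from ACC-MESO-1, an established human line of malignant pleural mesothelioma. Per the labels, total RNA was isolated on silica columns and 100 ng was labelled with a whole-transcript amplification kit. The 9 arrays form 3 groups of 3: a control shRNA (replicates 1 to 3), shLSD1 #1 (replicates 4 to 6) and shLSD1 #2 (replicates 7 to 9).

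The deposited values are log2 signal intensities, which the authors summarised per transcript cluster by RMA (robust multi-array average) in Affymetrix Expression Console 1.4. The log base was taken as 2, the RMA default. The library files and options of that software are not given in the sources used here. Values ran from 1.61 to 18.8, and 160 clusters exceeded 16, the log2 ceiling of a 16-bit scanner, so the highest values are relative and not raw intensities. Each array held 24351 probe set values, of which 2903 belonged to control probes and were set aside. The remaining 21448 transcript clusters were all tested without a filter on signal.

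Gene symbols came from the array's own annotation. A total of 17709 clusters carried 1 symbol, and 3739 clusters (17.4%) had none and entered the counts but no list. All 17709 named clusters had a gene ID in the RefSeq table for GRCh38.p14, which was used for names alone, and 0 symbols differed there. For 20 genes with several clusters, the cluster of highest mean signal stood for the gene.

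The test was fixed as limma's lmFit and eBayes on the deposited values in a single fit of the 3 groups, with a prior without trend (limma 3.58.1 in R 4.3.3). The contrasts were shLSD1 #1 minus control, shLSD1 #2 minus control, their mean minus control, and shLSD1 #1 minus shLSD1 #2. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all 21448 clusters, with a threshold of 0.05, and a second count asked for a change of at least 2-fold. Overlap between the hairpins was set against 100 simulated data sets with unchanged groups that shared the same 3 control arrays.

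A total of 24 gene lists with 615 distinct genes, 553 of them with a cluster on the array, were tested by limma's camera with a preset correlation of 0.01. Their 48 tests, 24 per hairpin, were adjusted together. Beside camera stand camera with an estimated correlation and fry. Camera compares a list with all other genes, whereas fry asks whether the list's own genes move, on balance, to 1 side. Some genes sit in more than 1 list, such as ATF3 (unfolded protein and immediate early) and CCN2 (TGF-beta and YAP/TEAD).

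Genes named in the text followed a rule: per hairpin the 6 named clusters with the largest rise and the 6 with the largest fall among those past the test whose 3 hairpin arrays all lay beyond all 3 control arrays. The rule added the 10 highest and 10 lowest clusters changed by both hairpins, and for the contrast between hairpins the 5 highest and 5 lowest past the test, of which there were 0. It further took up to 4 members per list past the test, and CDH1, CDH2, VIM, ZEB1, SNAI2, FN1 and RCOR1 in any case. These tests, thresholds, lists, naming rule and most alternatives were chosen before the data were examined. Contractile genes, genes that encode interferons, and interferon sensors and receptors were gathered into 3 further lists afterwards. The transcript of LSD1 itself is not analysed here.

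Signal over background was judged against 612 negative control probe sets. A gene counted as above the negative controls on an array when it exceeded the 95th percentile of these probes on that array, which lay between 6.93 and 7.54. Where all 3 arrays of a group fell below it, the group was set to the mean of its percentiles and the fold is given as a lower bound. Medians of lists were also computed with all values raised to 7.25, the mean percentile over the 9 arrays. The number of arrays limits the precision.

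The procedure was tested on simulated data with known changes. At a log2 change of 1 it called 71.6% of changed clusters for shLSD1 #1, 86.6% for shLSD1 #2 and 68.7% for the contrast between hairpins, and at 0.5 between 2.99% and 4.48%. It made 3, 5 and 2 false calls among 21448 clusters. Camera called any list in 1 of 50 draws of unchanged data. Genes were drawn independently there, so the draws do not show how camera behaves when the genes of a list are correlated.

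Alternatives tried were a second quantile normalization, subtraction of array medians, cyclic loess, omission of the third of clusters with the lowest mean, a trended robust prior, array weights, fits of only the groups compared and omission of each array in turn. Chosen after the data were seen were a fit without the 2 arrays of widest spread, a fit with the class of hybridization spike-in signal as a block, and a fit of only the arrays of high spike-in signal. Plots were drawn with matplotlib 3.10.9.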

Results

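Transcript levels were measured on 9 Clariom S arrays in ACC-MESO-1 cells, a line of malignant pleural mesothelioma, a tumour of the lining of the lung. The cells carried a control short hairpin RNA or 1 of 2 hairpins directed at LSD1, a histone demethylase that works in repressor complexes with RCOR1 and histone deacetylases. Each group had 3 arrays, numbered 1 to 3 for control shRNA, 4 to 6 for shLSD1 #1 and 7 to 9 for shLSD1 #2. The series asks how suppressing LSD1 bears on the mesenchymal character of mesothelioma cells. Over 21448 transcript clusters, array medians lay between 6.39 and 6.43 on the log2 scale. Between 42.0% and 46.2% of clusters exceeded the 95th percentile of the negative control probes. The transcript of LSD1 itself was not analysed here, so the extent of the knockdown was not checked. The labels do not say whether replicates are separate cultures, so each p-value measures the spread between arrays alone, which may be technical.

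Control arrays stood apart from the arrays of both hairpins. The root mean square log2 difference was 0.347 to 0.352 between control arrays, 0.526 to 0.585 between control and hairpin arrays, and 0.341 to 0.439 between arrays of different hairpins. The first principal component held 46.1% of the variance and separated control from hairpin arrays, and the second held 12.04%. The hybridization spike-ins, bacterial and phage transcripts that do not come from the cells, divided the arrays in another way. Their mean signal was 11.2 to 11.4 on the 3 control arrays and shLSD1 #2 replicates 7 and 9, and 10.8 to 10.9 on the 3 shLSD1 #1 arrays and shLSD1 #2 replicate 8. The gap between these classes was 0.249, against 0.127 for the next largest gap. All control arrays are in the high class and all shLSD1 #1 arrays in the low class, so a fit with the class as a block takes the class effect from shLSD1 #2 arrays alone. In that fit the shLSD1 #2 change is that of replicates 7 and 9 against control. The shLSD1 #1 change is this shLSD1 #2 change plus the difference of shLSD1 #1 from replicate 8. The block is therefore no separate check of shLSD1 #1.

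With shLSD1 #1, the 6 named genes with the largest fitted falls included the interferon-stimulated antiviral genes OAS1, OAS2 and MX1, and the 6 with the largest fitted rises included TAGLN, ACTA2 and CNN1, which encode proteins of the contractile actin cytoskeleton. Most of these 12 lay below the negative controls in a group, so their true order is not known. OAS1, which makes the messenger that activates RNase L, was at least 59.6-fold lower, with means of 13.07 ± 0.034 in control and 6.94 ± 0.17 in shLSD1 #1 arrays (log2, SD, n = 3). MX1, a GTPase that blocks viral replication, fell by 6.23 ± 0.14 on the log2 scale (SE, n = 3, adjusted p = 2.1e-08). XAF1 and IFI44L, both induced by interferon, were at least 29.6-fold and 12.5-fold lower. OAS2, a relative of OAS1, was at least 8.98-fold lower, and CFB, which encodes complement factor B, at least 14.5-fold. TAGLN, which encodes the actin-binding protein transgelin, was at least 18.2-fold higher, with means of 5.52 ± 0.71 and 11.59 ± 0.28. ACTA2, smooth muscle alpha-actin, was at least 16.4-fold higher, and CNN1, the actin-binding protein calponin, rose by 3.61 ± 0.17, with 1 of its 3 control arrays above the negative controls. ANKRD1, a YAP-responsive gene of muscle and stromal cells, was at least 6.85-fold higher, BAAT, a bile acid conjugating enzyme, at least 2.09-fold, and CPE, carboxypeptidase E, at least 1.78-fold. In a lower bound, the group below the negative controls is set to the mean of its negative control percentiles.

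By limma, 3385 clusters (15.8%) passed the adjusted threshold with shLSD1 #1, 1683 higher and 1702 lower, and 817 of them changed at least 2-fold, 354 higher and 463 lower. With the spike-in class as a block, 399 passed and 393 changed at least 2-fold, and 386 of the 3385 (11.4%) remained. The median absolute log2 change of the 3385 clusters went from 0.72 to 0.69 and their median SE from 0.14 to 0.25, so most calls ended because the error grew. Of the named members of the 24 gene lists, the shLSD1 #1 calls of HLA-C, HLA-E, IL32, ATF3, PLAUR, EXO1, CHAF1A, CCNB2, MKI67, CENPF, COX5A, NDUFB8, PMVK, FDPS, RPL27, DUSP1, CDH3, MSLN, GDF15, JUNB, CCN2, F3, NT5E, ITGA2, FERMT2, P4HA2, L1CAM, FN1, HDAC2, RBBP4 and RBBP7 ended with the block, at adjusted p between 0.0506 and 0.644.

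With shLSD1 #2, the same 6 genes had the largest fitted falls and the same 6 the largest fitted rises among named genes, and their true order is again not known. OAS1 was at least 59.8-fold lower, XAF1 at least 29.7-fold, CFB at least 14.6-fold, IFI44L at least 12.6-fold and OAS2 at least 9.01-fold, and MX1 fell by 6.35 ± 0.14 (SE, n = 3, adjusted p = 1.8e-08), with 2 of its 3 hairpin arrays above the negative controls. TAGLN was at least 13.6-fold higher, with a mean of 11.17 ± 0.23 (SD, n = 3), ACTA2 at least 10.9-fold, ANKRD1 at least 6.18-fold, BAAT at least 3.06-fold and CPE at least 1.69-fold, and CNN1 rose by 3.32 ± 0.17. limma called 2827 clusters (13.2%), 1406 higher and 1421 lower, and 714 changed at least 2-fold, 303 higher and 411 lower. Without control replicate 2, 933 were higher. With the spike-in class as a block, 1940 passed, and 1851 of the 2827 (65.5%) remained, and with only the 5 arrays of high spike-in signal 1450 passed. Of the named list members, the shLSD1 #2 calls of EXO1, CHAF1A, CCNB2, NDUFB8, RPL27, FERMT2, HDAC2, RBBP7, CDH1 and ZEB1 ended among those 5 arrays, at adjusted p between 0.0558 and 0.161.

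A change seen with both hairpins is less tied to either sequence, which is the reason for having 2. Among genes changed by both, OASL, an antiviral relative of the OAS enzymes, changed by -4.14 ± 0.17 with shLSD1 #1 and -4.48 ± 0.17 with shLSD1 #2 (SE, n = 3). IFI27, an interferon-induced mitochondrial protein, changed by -4.08 ± 0.13 and -4.45 ± 0.13. RSAD2, which encodes the antiviral enzyme viperin, changed by -3.82 ± 0.12 and -4.25 ± 0.12, and CMPK2, its neighbour and a nucleotide kinase, was at least 9.07-fold and 9.10-fold lower. TULP3, a trafficking factor of the primary cilium, rose by 2.88 ± 0.11 and 2.72 ± 0.11, and ALPG, an alkaline phosphatase whose probes may also read its close relative ALPP, by 2.77 ± 0.14 and 2.85 ± 0.14. ROPN1L, a sperm flagellum protein, was at least 3.12-fold and 2.72-fold higher. SLN, which encodes the calcium pump regulator sarcolipin, exceeded the negative controls on 2 shLSD1 #1 arrays, 1 shLSD1 #2 array and no control array, and no fold is given. All 20 genes named for a change with both hairpins, including those above, stayed past the threshold for both hairpins with the spike-in class as a block, and their log2 changes moved by at most 0.50. The block change of shLSD1 #1 is built on that of shLSD1 #2, so the hairpins are not separate checks there.

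In total 2238 clusters changed the same way with both hairpins, 1096 higher and 1142 lower, and 0 changed in opposite directions. Of these, 590 changed at least 2-fold with both, 257 higher and 333 lower. Independent calls would share 110 higher and 113 lower clusters. Both contrasts use the same 3 control arrays, which alone gave a correlation of log2 changes across clusters of 0.5002 in 100 simulations of unchanged groups, against 0.882 here. The simulations gave 0 shared calls, which follows from the absence of any change in them. They cannot show how many shared calls a peculiarity of the control arrays would give. Across clusters, which are not independent replicates, the covariance was 0.188 against 0.0185 in the simulations. The 3 control arrays are too few to divide between the contrasts, so part of the overlap may belong to the controls. With the block, 382 clusters passed for both hairpins, whose changes are not independent in that fit.

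**Figure D1:**
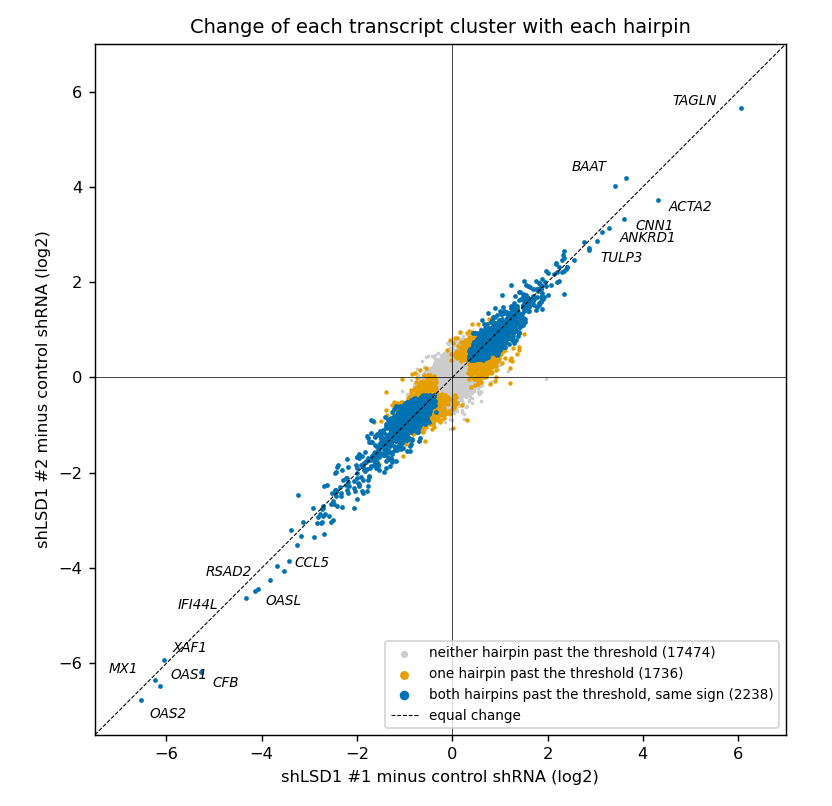
Log2 change against control shRNA with shLSD1 #1 (horizontal axis) and shLSD1 #2 (vertical axis) for each of the 21448 transcript clusters, coloured by whether neither, 1 or both contrasts passed adjusted p 0.05. Named points are genes of the naming rule, such as TAGLN at 6.07 and 5.65 and OAS2 at -6.54 and -6.77, fitted values that for genes below the negative controls are not bounds.

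The hairpins were hard to tell from each other. By limma 0 clusters differed between shLSD1 #1 and shLSD1 #2 at the adjusted threshold, with a smallest adjusted p of 0.446, and 1687 (7.87%) had an unadjusted p under 0.05, where chance gives 1072. A prior with trend and robust estimation called 42, of which 33 were higher with shLSD1 #1, with a largest absolute log2 difference of 0.89. For 94.8% of clusters the 95% interval of the difference lay within 1 of 0 on the log2 scale. Genes called by either hairpin numbered 3974, of which 56.3% passed for both and 99.02% had the same sign. The shared control arrays alone favour the same sign: over all clusters 79.1% had it, against a mean of 66.7% in the simulations of unchanged groups.

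**Figure D2:**
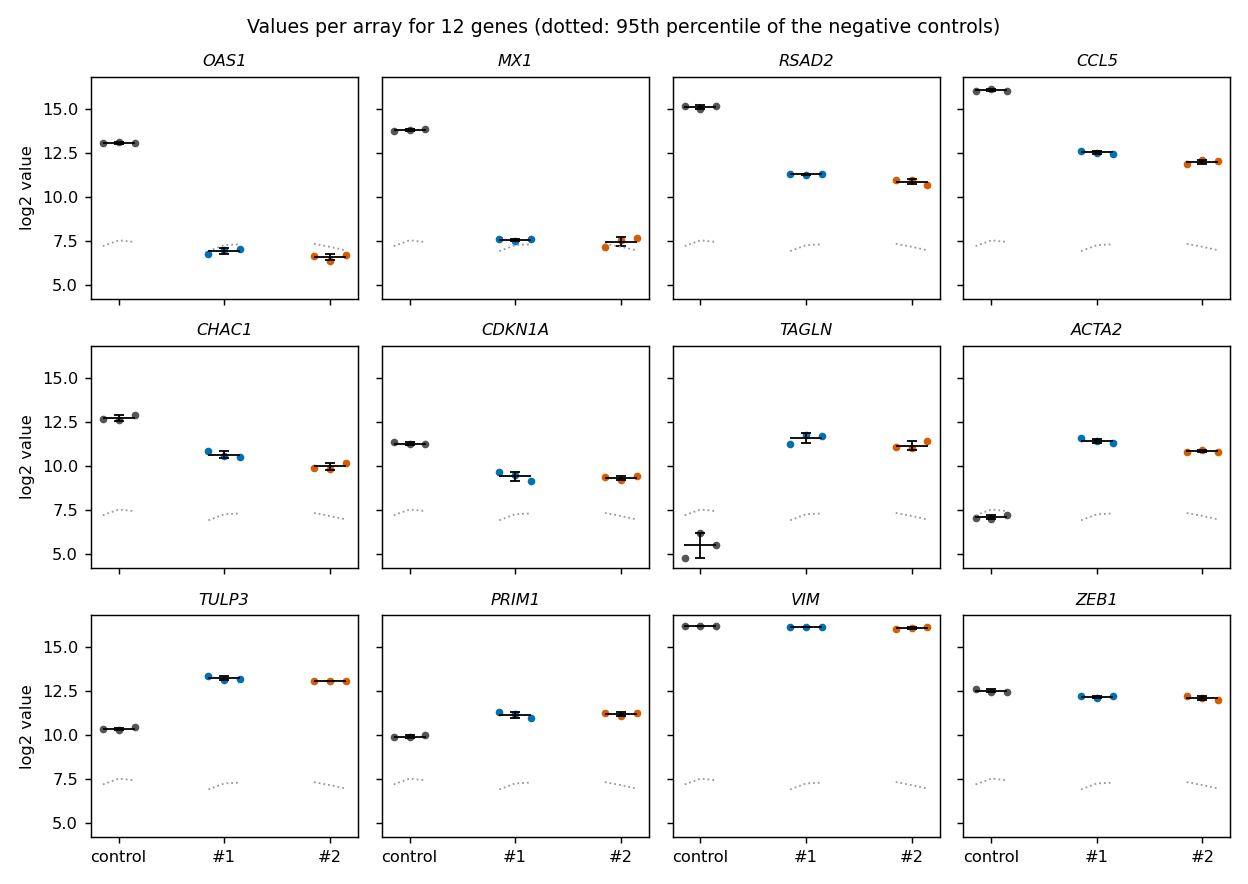
Log2 signal of 12 genes on each of the 9 arrays, by group, with points for arrays, bars for the group mean, whiskers for 1 SD and a dotted line for the negative control 95th percentile. OAS1 lies near 13.07 in control arrays and below the dotted line in every hairpin array, TAGLN shows the opposite, and the VIM values of the 3 groups overlap or lie close together.

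In the gene lists that follow, paired log2 changes give shLSD1 #1 first and shLSD1 #2 second, each from 3 arrays per group, and the SE of the named genes lay between 0.097 and 0.35, with a median of 0.14. The interferon response list fell with both hairpins. Of its 35 members on the array, 2 lay below the negative controls on all 9 arrays. Counting these, 34 and 35 were lower and 0 higher, and all 35 were lower with each hairpin when adjusted over the list alone. The median change was -2.49 and -2.66 (camera adjusted p = 3.95e-51 and 3.78e-59), and -2.34 and -2.49 with low values raised to the negative controls. Camera with an estimated correlation gave adjusted p = 0.00151 for each hairpin. The exception with shLSD1 #1 was IFITM3, which encodes an inhibitor of viral entry, at -0.32 and -0.36, named here after its values were seen. The mean signal of the list was 12.30 ± 0.022 in control, 9.51 ± 0.026 in shLSD1 #1 and 9.27 ± 0.083 in shLSD1 #2 arrays (SD, n = 3). With the block the medians were -2.50 and -2.60. Among arrays of high spike-in signal, which give the same shLSD1 #2 changes as the block, 33 members were lower with shLSD1 #2. Close relatives such as the OAS, IFIT and IFITM genes may share probe signal, so single members are less certain than the list.

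The lists of MHC class I antigen presentation and of NF-kB and cytokine genes were called lower than other genes with both hairpins. In the MHC class I list, 8 and 10 of 16 members were lower and 0 higher, and 10 and 11 were lower adjusted over the list alone. Its median was -0.67 and -0.70 (adjusted p = 1.48e-07 and 2.47e-08), with adjusted p = 0.0843 and 0.0719 with an estimated correlation. TAP1, which carries peptides to MHC molecules, changed by -1.39 and -1.55, the antigen-presenting HLA-C by -1.36 and -1.28, HLA-E by -1.25 and -1.23, and HLA-F by -1.13 and -1.25, where HLA genes may share probe signal. With the block the MHC medians were -0.70 and -0.72. In the NF-kB and cytokine list, 9 and 9 of 26 members were lower and 0 higher, and 10 and 12 were lower adjusted over the list alone (adjusted p = 4.29e-05 and 3.58e-07). Camera with an estimated correlation gave adjusted p = 0.0481 and 0.0246. CCL5, a chemokine that draws T cells, changed by -3.54 and -4.06 from a control mean of 16.07, NFKBIA, the inhibitor of NF-kB that NF-kB itself induces, by -1.36 and -1.51, and IL32, a pro-inflammatory cytokine, by -1.39 and -1.32. IL6 was at least 1.74-fold and 1.75-fold lower. Because 14 of the 26 members lay below the negative controls on all 9 arrays, the list's median of -0.15 and -0.34 became 0 and 0 with low values raised to the negative controls, and with the block it was -0.42 and -0.49.

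The unfolded protein and amino acid response list was called lower with both hairpins. Of 23 members, 13 and 12 were lower and 1 and 1 higher, and 14 and 12 were lower and 1 and 1 higher adjusted over the list alone. The median was -0.63 and -0.61 (adjusted p = 2.47e-08 and 1.48e-07), with adjusted p = 0.0600 and 0.0600 with an estimated correlation, and -0.48 and -0.63 with the block. CHAC1, which degrades glutathione, changed by -2.07 and -2.73, DDIT4, an inhibitor of mTORC1 signalling, by -2.33 and -2.42, PHGDH, the entry enzyme of serine synthesis, by -2.03 and -1.85, and ASNS, asparagine synthetase, by -1.43 and -1.31. ATF3, a stress-induced transcription factor, was the member that rose, by 0.85 and 1.05.

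The DNA replication and mitosis lists were called higher with both hairpins, and most of their members did not pass. In the DNA replication list, 13 and 12 of 39 members were higher and 0 lower, and 15 and 12 were higher adjusted over the list alone. Its median was 0.19 and 0.21 (adjusted p = 0.000770 and 0.000260), with adjusted p = 0.109 and 0.0977 with an estimated correlation, and 0.30 and 0.20 with the block. PRIM1, the primase subunit that starts DNA strands, rose by 1.22 and 1.29, EXO1, a DNA repair exonuclease, by 1.24 and 1.10, and CHAF1A, which loads histones on new DNA, by 1.14 and 1.00, with 2 of 3 control arrays above the negative controls. In the mitosis list, 9 and 3 of 35 members were higher and 1 and 0 lower, and 9 and 3 were higher and 2 and 0 lower adjusted over the list alone. The median was 0.20 and 0.18 (adjusted p = 0.00320 and 0.00992), with adjusted p = 0.247 and 0.308 with an estimated correlation, and 0.26 and 0.19 with the block. The mitosis call for shLSD1 #2 ended without shLSD1 #2 replicate 9 (adjusted p = 0.0586). CCNB2, a mitotic cyclin, rose by 0.84 and 0.61, whereas MKI67, a marker of cycling cells, and CENPF, a kinetochore protein, rose by 0.72 and 0.84 with shLSD1 #1 and had 0.39 and 0.47 with shLSD1 #2, short of the threshold at adjusted p = 0.054 and 0.062. MKI67 with shLSD1 #2 passed with a second quantile normalization (0.0468), without the clusters of lowest mean (0.0240), with the trended robust prior (0.00484) and with array weights (0.0434), and CENPF without the clusters of lowest mean (0.0326), with the trended robust prior (0.0106) and without control replicate 3 (0.0234). CDKN1A, which encodes the cell cycle inhibitor p21 and sits in the p53 target list, changed by -1.86 ± 0.15 and -1.95 ± 0.15.

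The lists closest to the question of the series, mesenchymal and epithelial, were not called. Of 31 mesenchymal members, 4 and 4 were higher and 9 and 10 lower, and 6 and 5 were higher and 11 and 12 lower adjusted over the list alone (adjusted p = 0.200 and 0.184). The median was -0.12 and -0.062 and the test pointed down, whereas the mean was 0.092 and 0.055 because of the rises in TAGLN and ACTA2. FAP, a protease of activated fibroblasts, changed by -1.999 and -2.008, with 1 array of each hairpin above the negative controls, and THY1, a surface protein of mesenchymal cells, by -1.68 and -1.64. FN1, fibronectin, changed by -0.68 and -1.27, and its shLSD1 #1 call ended without control replicate 1 (adjusted p = 0.0508), shLSD1 #1 replicate 4 (0.0595) or shLSD1 #1 replicate 6 (0.0546). VIM, the intermediate filament vimentin, had log2 changes of -0.07 ± 0.097 and -0.12 ± 0.097 (adjusted p = 0.695 and 0.490), CDH2, N-cadherin, of -0.25 and 0.10 (adjusted p = 0.265 and 0.720), and SNAI2, an epithelial-mesenchymal transition factor, of -0.23 and -0.26 (adjusted p = 0.246 and 0.218). ZEB1, another such factor, had -0.35 and fell by 0.41 with shLSD1 #2 (adjusted p = 0.0655 and 0.0429), a call that ended in each of the 8 fits that left out 1 array other than shLSD1 #1 replicate 5, at adjusted p between 0.0580 and 0.136, as well as with a second quantile normalization (0.0722) and in a fit of only the groups compared (0.0734). With shLSD1 #1, ZEB1 passed without the clusters of lowest mean (0.0299) and with the trended robust prior (0.00739). Of 29 epithelial members, 3 and 4 were higher and 3 and 3 lower, and 5 and 4 were higher and 3 and 3 lower adjusted over the list alone (adjusted p = 0.660 and 0.983), with medians of 0.10 and 0.021 and a test that pointed down for shLSD1 #2. The epithelial medians were 0.013 and -0.025 with the block, and 0 and 0 with low values raised to the negative controls. CDH3, P-cadherin, changed by -1.10 and -1.29. CDH1, E-cadherin, lay below the negative controls on all 9 arrays, as did 17 epithelial members in total. It still counts among the 4 higher with shLSD1 #2, a call that ended without control replicate 1 (adjusted p = 0.0542) or shLSD1 #2 replicates 7, 8 or 9 (0.0642, 0.0600 and 0.0704). With shLSD1 #1, CDH1 passed without the clusters of lowest mean (0.0310) and with the trended robust prior (0.0271).

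**Figure D3:**
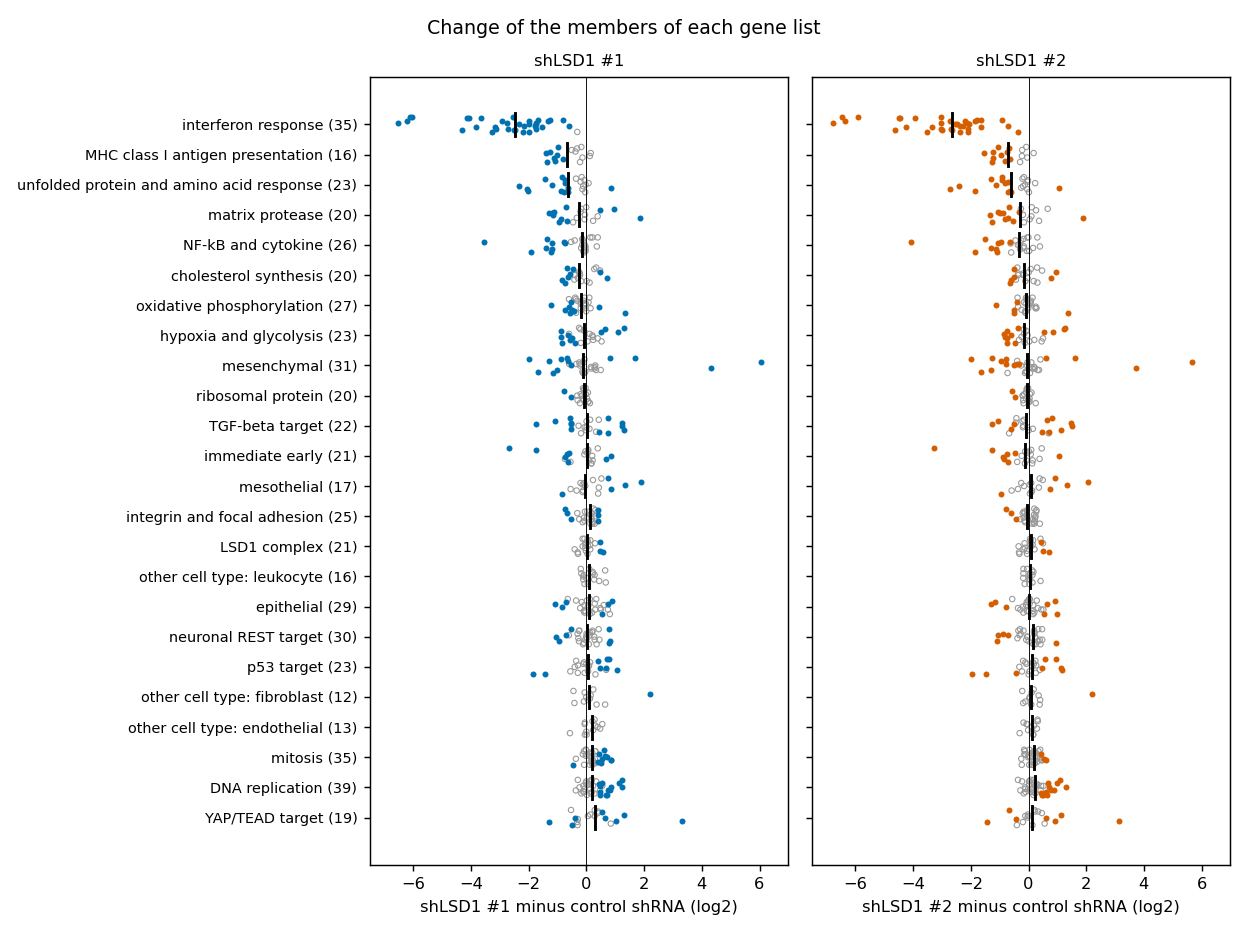
Log2 change of each member on the array of the 24 gene lists with shLSD1 #1 and shLSD1 #2, with filled points for members past adjusted p 0.05, open grey points for the others and a black bar for the list's median. The interferon response list lies lowest, with medians of -2.49 and -2.66, and the mesenchymal and epithelial lists hold members on both sides of 0.

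The matrix protease list was called lower with both hairpins. Of 20 members, 8 and 10 were lower and 3 and 1 higher, also when adjusted over the list alone (adjusted p = 0.00508 and 0.00129), with adjusted p = 0.0719 and 0.0600 with an estimated correlation. The median was -0.27 and -0.31, and -0.52 and -0.38 with the block, whereas it was 0 and 0 with low values raised to the negative controls, since 10 members lay below them on all 9 arrays. CTSL, the lysosomal protease cathepsin L, changed by -1.17 and -1.33, and PLAUR, the urokinase receptor, by -1.29 and -0.99. TIMP3, an inhibitor of matrix proteases, rose by 1.86 and 1.89. The list as written also holds the inhibitors TIMP1 and TIMP2, so its median and test mix proteases with inhibitors. Of 25 integrin and focal adhesion members, 3 and 0 were higher and 3 and 3 lower, the same adjusted over the list alone (adjusted p = 0.712 and 0.822), with ITGA2, a collagen receptor subunit, at -0.76 and -0.80 and FERMT2, an integrin activator, at -0.66 and -0.62.

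The oxidative phosphorylation, cholesterol synthesis and ribosomal protein lists passed with shLSD1 #1 and missed the threshold with shLSD1 #2. In camera's test of the difference between hairpins they had adjusted p = 0.00161, 0.0265 and 0.444, and none of these passed with an estimated correlation (0.146, 0.148 and 0.736). The oxidative phosphorylation list had 7 and 4 of 27 members lower and 2 and 1 higher, and 10 and 6 lower and 2 and 1 higher adjusted over the list alone, with medians of -0.20 and -0.080 (adjusted p = 0.00508 and 0.310). For shLSD1 #1 it had adjusted p = 0.102 with an estimated correlation and 0.0820 with the block, where the medians were -0.17 and -0.044. Its members COX5A and NDUFB8, respiratory chain subunits, changed by -1.24 and -1.13 and by -0.75 and -0.51, and COX7C, another subunit, rose by 1.35 and 1.38. Without control replicate 1, control replicate 2, control replicate 3, shLSD1 #2 replicate 7 or shLSD1 #2 replicate 8, the shLSD1 #2 call of NDUFB8 ended, at adjusted p up to 0.0916. Cholesterol synthesis had 6 and 4 of 20 members lower and 2 and 2 higher, and 9 and 6 lower and 4 and 3 higher adjusted over the list alone, with medians of -0.24 and -0.15 (adjusted p = 0.0416 and 0.322). For shLSD1 #1 it had adjusted p = 0.127 with an estimated correlation and 0.280 with the block, where the medians were -0.11 and -0.14, and 0.0584, 0.0583 and 0.0527 without control replicate 1, control replicate 3 and shLSD1 #1 replicate 4. FDPS, a synthase of the mevalonate pathway, changed by -0.83 and -0.61, and PMVK, a kinase of the same pathway, rose by 0.73 and 0.78. Ribosomal protein genes had 2 and 2 of 20 members lower and 0 higher, the same adjusted over the list alone, with medians of -0.095 and -0.059 (adjusted p = 0.0433 and 0.184). For shLSD1 #1 the ribosomal list had adjusted p = 0.506 with an estimated correlation and 0.327 with the block, where the medians were -0.040 and -0.041. It also ended without control replicate 2, control replicate 3, shLSD1 #1 replicates 4 or 6, or shLSD1 #2 replicates 7 or 9, at adjusted p between 0.0505 and 0.140. RPL27, a protein of the large subunit, changed by -0.78 and -0.58.

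Immediate early genes, the first to respond to growth signals, passed with shLSD1 #2 and missed the threshold with shLSD1 #1, with no difference called between the hairpins (adjusted p = 0.502). The shLSD1 #2 call had adjusted p = 0.310 with an estimated correlation. Of 21 members, 6 and 7 were lower and 2 and 1 higher, and 8 and 7 were lower and 3 and 3 higher adjusted over the list alone (adjusted p = 0.167 and 0.0416). The median was 0.034 and -0.12 and the mean -0.27 and -0.33, so for shLSD1 #1 the median differs in sign from the mean and from the test, which pointed down. With low values raised to the negative controls the median was 0 and 0, and 8 of the 21 members lay below them on all 9 arrays. For shLSD1 #2 the list had adjusted p = 0.101 with the block, where the medians were -0.080 and -0.096. It had 0.0740, 0.0570, 0.0698 and 0.0895 without control replicate 2, control replicate 3, shLSD1 #2 replicate 7 and shLSD1 #2 replicate 8. KLF4, a transcription factor of differentiation and pluripotency, was at least 2.53-fold and 2.54-fold lower, and DUSP1, a MAP kinase phosphatase, changed by -0.75 and -0.88.

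The other lists were not called for either hairpin. Of 23 p53 target genes, 6 and 5 were higher and 2 and 3 lower, and 7 and 5 were higher and 5 and 3 lower adjusted over the list alone (adjusted p = 0.938 and 0.582). TNFRSF10B, a death receptor, changed by -1.42 and -1.46, and GDF15, a stress-induced cytokine, rose by 1.07 and 1.14. Of 22 TGF-beta target genes, 6 and 7 were higher and 6 and 4 lower, and 7 and 8 were higher and 6 and 7 lower adjusted over the list alone (adjusted p = 0.822 and 0.822), with ID2, an inhibitor of differentiation factors, at 1.23 and 1.51, the receptor TGFBR1 at 1.23 and 1.47 and JUNB, an AP-1 factor above the negative controls on 2 of 3 shLSD1 #1 arrays, at -1.76 and -1.28. Of 19 YAP/TEAD targets, 5 and 4 were higher and 3 and 3 lower, and 6 and 4 were higher and 5 and 4 lower adjusted over the list alone (adjusted p = 0.337 and 0.465), with the matricellular gene CCN2 at 1.30 and 1.11, the nucleotidase NT5E at 1.02 and 0.93 and the coagulation factor receptor F3 at -1.31 and -1.43. Of 23 hypoxia and glycolysis genes, 4 and 4 were higher and 7 and 8 lower, and 5 and 5 were higher and 9 and 9 lower adjusted over the list alone (adjusted p = 0.411 and 0.184), with the vasodilator gene ADM at 1.29 and 1.25 and the collagen hydroxylase P4HA2 at -0.90 and -0.80. Of 17 mesothelial genes, 4 and 4 were higher and 1 and 1 lower, and 6 and 4 were higher and 2 and 1 lower adjusted over the list alone (adjusted p = 0.375 and 0.203), with the growth factor HBEGF, above the negative controls on 2 of 3 control arrays, at 1.88 and 2.07 and mesothelin, MSLN, at -0.85 and -0.95. Of these 17 genes, 11 lay below the negative controls on all 9 arrays.

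Of 21 members of LSD1 complexes, 3 and 3 were higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.748 and 0.519). These were the histone-binding RBBP4 (0.57 and 0.72) and RBBP7 (0.48 and 0.42) and the deacetylase HDAC2 (0.47 and 0.50), and each lost at least 1 call when single arrays were left out, at adjusted p up to 0.109, 0.129 and 0.0673 without control replicate 1, shLSD1 #2 replicate 7 and control replicate 3. RCOR1, the partner of LSD1, had 0.30 ± 0.16 and 0.50 ± 0.16 (adjusted p = 0.267 and 0.0772, and 0.0439 with shLSD1 #2 without the clusters of lowest mean), with 1 of 3 control arrays above the negative controls. Of 30 neuronal genes that the repressor REST silences, 3 and 1 were higher and 4 and 4 lower, and 3 and 1 were higher and 5 and 4 lower adjusted over the list alone (adjusted p = 0.871 and 0.938), with the adhesion molecule L1CAM at 0.79 and 0.96, and 23 members lay below the negative controls on all 9 arrays. Leukocyte markers (adjusted p = 0.544 and 0.938) and endothelial markers (adjusted p = 0.547 and 0.588) had 0 members past the threshold, also adjusted over the list alone, with 13 of 16 and 12 of 13 below the negative controls on all 9 arrays. Fibroblast markers had 1 of 12 higher with each hairpin, the same adjusted over the list alone: LUM, a collagen-binding proteoglycan, at 2.19 and 2.21 with 1 of 3 control arrays above the negative controls (adjusted p = 0.581 and 0.337). Of the 12 fibroblast markers, 8 lay below the negative controls on all 9 arrays. Median and mean also differed in sign for the mesothelial and p53 target lists with shLSD1 #1, the TGF-beta target list with shLSD1 #2 and the neuronal list with both, and in each the test followed the mean except for p53 targets, where it followed the median.

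**Figure D4:**
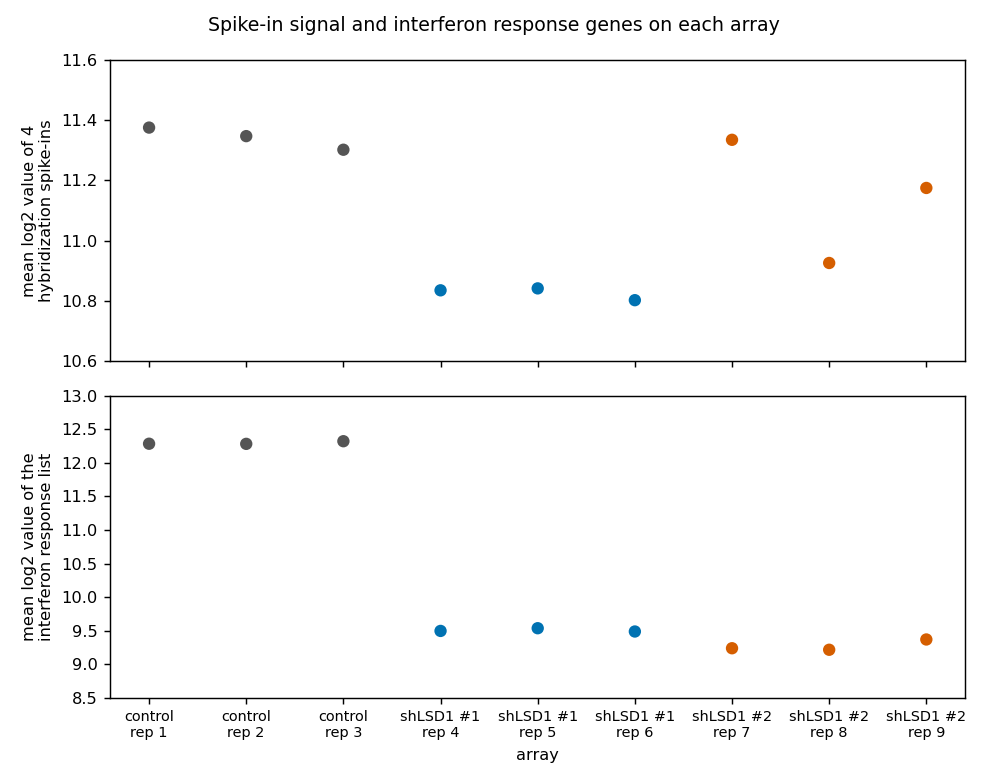
Mean log2 signal of the 4 bacterial and phage hybridization spike-ins (upper panel) and of the 35 interferon response genes (lower panel) on each of the 9 arrays, coloured by group. The spike-in signal is lower on shLSD1 #1 replicates 4 to 6 and shLSD1 #2 replicate 8, whereas the interferon genes are lower on all 6 hairpin arrays, including shLSD1 #2 replicates 7 and 9.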

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

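Tests chosen only after the result was seen are the interferon list among arrays of high spike-in signal, the fits with the spike-in class as a block, TAGLN, ACTA2 and CNN1 among arrays of high spike-in signal, and the question whether the interferon response was peculiar to the control cultures. The lists of genes that encode interferons and of contractile genes were also put together only after the falls and rises they address were seen. Each list result in the rest of this paragraph was picked out because the list's change differed between the hairpins by limma's camera on the contrast of shLSD1 #1 with shLSD1 #2. The interferon response list lay higher with shLSD1 #1, by a median of 0.23 on the log2 scale and in 30 of 35 members (adjusted p = 1.78e-08), with adjusted p = 0.146 with an estimated correlation and a smallest member adjusted p of 0.479. With the spike-in class as a block the median was 0.28 (camera adjusted p = 2.14e-08). For each list the block contrast of the hairpins rests on replicate 8, the 1 shLSD1 #2 array of the low class. Cholesterol synthesis lay lower with shLSD1 #1, by a median of -0.12 and with 6 of 20 members higher (adjusted p = 0.0265), with adjusted p = 0.148 with an estimated correlation and 0.491 with the block. Oxidative phosphorylation lay lower with shLSD1 #1, by a median of -0.127 and with 4 of 27 members higher (adjusted p = 0.00161), with adjusted p = 0.146 with an estimated correlation and 0.185 with the block.

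The pattern a biologist would follow up first is the fall of interferon response genes with both hairpins. A batch of arrays seen in the hybridization spike-ins would leave little change between arrays of the same class, and the tables argue against it: within the 5 arrays of high spike-in signal the list's median change with shLSD1 #2 was -2.60, with 33 of 35 members lower. Interferon made by the control cells stays open, since 0 of 9 genes that encode interferons fell with both hairpins but all 9 lay below the negative controls on every array, where a change could not be seen. An interferon response peculiar to the control cultures, rather than a loss of it with LSD1, may also give this pattern, and the series has 1 control shRNA and 0 groups without any hairpin, so these cannot be told apart. Loss of LSD1 itself, the biological difference the design names, stays open with them.

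No cluster differed between the hairpins by limma at the adjusted threshold, where 1687 had an unadjusted p under 0.05 and a prior with trend and robust estimation called 42. A spread of the arrays too wide to show differences of 2-fold was set against the 95% interval of the difference, which lay within 1 of 0 on the log2 scale for 94.8% of clusters. Only 42.0% to 46.2% of clusters exceeded the negative controls on an array, and below them a true difference may be compressed. In simulated data the contrast called 68.7% of log2 changes of 1. The intervals show a narrow spread for most clusters, but a missed 2-fold difference stays open, above all at low signal. Hairpin labels exchanged between arrays may also hide a difference, and this stays open: 2 of the other splits of the 6 hairpin arrays gave more clusters at an unadjusted p under 0.05 than the labelled split, at most 2106 against 1687. That split sets replicates 5, 7 and 9 against 4, 6 and 8, and replicates 5 and 9 also have the widest spread of values (SD 3.42 and 3.43), so a difference between arrays that has nothing to do with labels would give the same count. In the mean scores of the 24 gene lists, the labelled split separated 4 lists, with interferon at 9.49 to 9.54 on shLSD1 #1 and 9.21 to 9.37 on shLSD1 #2, and the split that gave 2106 separated 7, so the scores do not settle it.

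The rise of TAGLN, ACTA2 and CNN1 with both hairpins was set against a list of smooth muscle contractile genes written after the data were seen. If the contractile genes rose as a group, over 1 in 2 of the other members on the array would be higher with both hairpins, and 7 of 17 were, of 20 on the array in all. That count lies between the bounds set for and against, but 5 of the 17 lay below the negative controls on all arrays, where a small rise would not be seen. Of the 12 above the negative controls on any array, 7 were higher with both hairpins, over 1 in 2, and 1 with the spike-in class as a block. The answer turns on which genes are counted, so a rise of the smooth muscle contractile genes as a group may or may not be part of the pattern. With the spike-in class as a block, 4 of the 10 contractile genes called for both hairpins stayed called for both, while the median absolute log2 change of the 10 with shLSD1 #1 went from 0.96 to 0.90 and the median SE from 0.14 to 0.26. Of the 6 lost calls, MYLK (0.97 to 0.58), TPM1 (0.94 to 0.74) and CALD1 (0.58 to 0.51) also had smaller changes, whereas SYNPO2 had a larger one (1.53 to 2.43). A batch of arrays seen in the spike-ins is argued against for TAGLN, ACTA2 and CNN1: within the arrays of high spike-in signal the smallest of their log2 changes with shLSD1 #2 was 3.02, with low values raised to the negative controls.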

How the results depend on the processing

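Tests chosen after the data were seen are those without the 2 arrays of widest spread, with the spike-in class as a block and with only the arrays of high spike-in signal. No paired analysis was possible because the array numbers run from 1 to 9 across the series and no number is shared between groups, and no alternative gave a value for the knockdown of LSD1 itself. No result reversed. Total counts stayed within 1.5 times their value under every alternative but those named here: the contrast between hairpins rose from 0 to 42 with the trended robust prior. With the spike-in class as a block, shLSD1 #1 fell to 399 (393 at least 2-fold), both hairpins to 382 and their mean to 1225. The SE grew while median log2 changes held, but the shLSD1 #1 change there is built on the shLSD1 #2 arrays. With only arrays of high spike-in signal shLSD1 #2 fell to 1450, with 2 arrays in place of 3. Leaving out each array in turn gave 2375 to 3275 for shLSD1 #1, 1918 to 2710 for shLSD1 #2, 1579 to 1944 for both and 0 for the difference. Median log2 change over all clusters was at most 0.030 under each scaling. For the lists, the cause of the following changes was not tested, and values are camera adjusted p unless fry is named. With an estimated correlation, shLSD1 #1 had 0.0843 for MHC class I, 0.109 for DNA replication, 0.247 for mitosis, 0.0719 for matrix protease, 0.127 for cholesterol, 0.102 for oxidative phosphorylation, 0.0600 for unfolded protein and 0.506 for ribosomal genes. shLSD1 #2 had 0.0719, 0.0977, 0.308 and 0.0600 for the first 4 of these, 0.0600 for unfolded protein and 0.310 for immediate early genes. With an estimated correlation the interferon list had 0.00151 for each hairpin and the NF-kB list 0.0481 and 0.0246, so their calls held. Without the 33.3% of clusters of lowest mean, cholesterol and ribosomal genes with shLSD1 #1 both had 0.101, and immediate early genes with shLSD1 #2 0.0867. Without the 2 arrays of widest spread, mitosis and cholesterol with shLSD1 #1 and mitosis with shLSD1 #2 each had 0.0576. With the block, shLSD1 #1 had 0.280 for cholesterol, 0.0820 for oxidative phosphorylation and 0.327 for ribosomal genes, and immediate early genes with shLSD1 #2 had 0.101, or 0.100 among arrays of high spike-in signal. Leaving out each array in turn gave 0.0404 to 0.0584 for cholesterol and 0.00923 to 0.140 for ribosomal genes with shLSD1 #1, and 0.00786 to 0.0586 for mitosis and 0.0219 to 0.0895 for immediate early genes with shLSD1 #2. Fry, which does not compare a list with other genes, passed more lists: mesothelial (0.00415 and 0.00279), hypoxia (0.0122 and 0.00494) and fibroblast (0.0498 and 0.0294) with both hairpins, YAP/TEAD (0.0340) and immediate early (0.00281) with shLSD1 #1, and TGF-beta (0.0226) and cholesterol (0.00364) with shLSD1 #2. For named genes, leaving out arrays ended 105 calls, added 3 and left 1674 as they were, and other settings ended 103, added 16 and left 1760. Signal limits the lists in which most members lie below the negative controls, on all 9 arrays, such as the epithelial (17 of 29) and neuronal (23 of 30) lists. The mesothelial (11 of 17) and fibroblast (8 of 12) lists that fry passed are also among them.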

Other observations

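The lists of interferon sensors and receptors and of contractile genes were chosen only after the falls of interferon genes and the rise of TAGLN were seen, whereas the counts over other splits of the arrays were planned. Among 13 interferon sensors and receptors, 5 were lower with both hairpins and 0 higher. STING1, the adaptor that answers cytosolic DNA, changed by -2.19 ± 0.16 and -2.20 ± 0.16 on the log2 scale (shLSD1 #1 and shLSD1 #2, SE, n = 3), CGAS, the DNA sensor upstream of it, by -1.09 and -0.60, the transcription factor IRF1 by -1.15 and -1.02, and the receptor chain IL10RB by -1.22 and -1.09. TLR3, a sensor of double-stranded RNA, also passed but lay below the negative controls on all arrays. With the spike-in class as a block, 1 of the 5, STING1, stayed past the threshold for both hairpins, and 4 stayed for shLSD1 #2, while the median absolute log2 change of the 5 with shLSD1 #1 went from 1.15 to 1.13 and the median SE from 0.16 to 0.29, with smaller changes for TLR3, below the negative controls, and for CGAS (-1.09 to -0.77). The interferon receptor chain IFNAR1 had 0.45 and 0.42 (adjusted p = 0.0773 and 0.111), IFNAR2 0.01 and 0.01, and JAK1, TBK1 and MAVS did not pass for either hairpin.

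Among 20 contractile genes, 10 were higher with both hairpins and 0 lower with both. Beside TAGLN, ACTA2 and CNN1 these were MYL9, a myosin light chain (0.94 and 0.69), the tropomyosins TPM1 (0.94 and 1.01) and TPM2 (0.82 and 0.66), the actin-binding CALD1 (0.58 and 0.56) and CNN2 (0.76 and 0.54), the myosin kinase MYLK, at least 1.11-fold and 1.02-fold higher, and SYNPO2, which exceeded the negative controls on 1 array only. With the block, 4 of the 10 stayed past the threshold for both hairpins, TAGLN, ACTA2, CNN1 and MYL9, and 7 stayed for shLSD1 #2. SRF, the transcription factor that drives many of them, had 0.33 and -0.16 (adjusted p = 0.234 and 0.618).

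Other divisions of the same arrays were fitted to ask whether chance groups give counts as large. For each hairpin against control, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split gave 3385 clusters for shLSD1 #1 (817 at least 2-fold) and 2827 for shLSD1 #2 (714), the highest other split 0 in each case, and 1 of 10 splits reached the real count each time. For the contrast between hairpins the splits are as few, and 3 of 10 reached the real 1687 clusters at an unadjusted p under 0.05, with 2106 in the highest other. For clusters changed the same way by both, 1 of 100 drawn splits, the labelled one, reached 2238. Of the others, 1 kept the 3 control arrays together with hairpin arrays exchanged and gave 2202. Splits with another choice of control arrays gave at most 0. These counts argue against a chance choice of the control arrays and do not test the division into 2 hairpins. For the mean of both hairpins in a fit of 2 groups, 1 of 84 splits reached 3835, with 1 in the highest other. This argues against a chance division of the arrays, with the smallest share that 84 splits can give. If the arrays of a group share 1 culture, neither count excludes a chance difference between cultures.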
